A study of Rattus norvegicus with 8 samples.

How the data were processed

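Liver RNA of male Wistar/ST rats was measured on 8 Agilent 1-colour (Cy3) arrays, 4 from control rats and 4 from rats given Eucommia ulmoides leaf extract in the drinking water. All rats received a high-fat diet and fructose-rich water for 5 weeks, and 500 ng of total RNA was labelled per array, per the labels' protocols. The labels number 4 samples in each group and describe liver taken from each rat. Nothing else states that each array came from a different rat, so p-values measure the spread between these samples.

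The deposited scanner files hold intensity values made with Agilent Feature Extraction 10.1.1.1, per the file headers and the submitters' processing notes. The processed signal in them is background-subtracted and detrended within each array, per the file headers, and is not normalized between arrays. The flags in the same deposited files, of another kind than intensities, mark control spots, spots well above background, saturated spots and outlier spots. The deposited series table was compared with the scanner files spot by spot. Its values equalled the processed signal at 100% of 43379 non-control spots on every array, with a linear scale and no centring, and its column medians ran from 26.3 to 32.0.

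Signals were put on the log2 scale and each array's 75th percentile was subtracted. A value of 0 is therefore the signal at that percentile. Control spots and spots marked as outliers were left out, spots of a probe were averaged, and no spot was saturated. A probe was kept if it was well above background on at least 4 of the 8 arrays, whichever group they belonged to, which left 27694 of 41012 probes. The files name probes by accession. Accessions were matched without versions to a RefSeq gene table of assembly GRCr8, which named 16336 probes (39.8%) with 13031 symbols. The array design uses another build, so no coordinates are given. A gene is represented by its probe with the highest mean signal, and an unnamed probe is a feature of its own. In total 24194 features, called genes here, were tested, 9895 of them with an established symbol.

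Groups were compared with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are Eucommia minus control on the log2 scale, with standard errors from the fit, and group means are given with the SD of 4 arrays. Where a gene was not well above background with any probe on any array of a group, its fold is a lower bound: the other group's mean was set against the higher of the dim probe's signal and the lowest signal among probes well above background on each array. 50 gene lists, 13 of them cell type markers, were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, which tests whether a list's genes move on balance one way. The named genes are the 10 with the largest change in each direction among those past the threshold whose groups did not overlap, the 4 members with the smallest p of each list past the threshold and of the 3 fatty acid oxidation lists, and up to 2 members of other lists. The lists, the rule, the tests of genes and lists and the alternatives were fixed before the data were examined, but not the bounds of the tests of explanations. Genes named under any other rule are said to be chosen after their values were seen. Sensory receptor genes were picked out by symbol (odorant, vomeronasal, trace amine and taste receptors), also after the values were seen. A few named genes are not reported here.

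The test was checked on simulated data for the Eucommia against control comparison, with 24194 genes. It called 100% of genes changed by a log2 value of 2, 64% of those changed by 1, 52% of those changed by -1 and 8% of those changed by 0.5, beside 5 unchanged genes. The simulated noise was normal and independent between genes, with no difference between slides and no floor. The check therefore says nothing about false calls that come from the slides. The number of arrays limits the precision.

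Alternatives were quantile normalization, median centring, a percentile over probes above background on all arrays, normexp background correction with an offset of 50, the series table, other filters on dim probes, the mean over probes, every probe on its own, trended robust variance, array weights, the replicate number as a block, and each array left out in turn. Normexp used the spots' median signal in place of the mean signal. Cyclic loess normalization and a restriction to bright genes were added after seeing the data. All control arrays lay on slide 1 and all Eucommia arrays on slide 2, each scanned in a session of its own, so a slide block could not be fitted.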

Results

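Gene expression was measured in the liver of rats on a high-fat diet with fructose-rich drinking water, with (4 arrays) or without (4 control arrays) an extract of Eucommia ulmoides leaves, a tree whose leaves are used for tea. The comparison asks which liver genes differ between the groups, and fatty acid oxidation was the process of interest fixed in advance. On the control arrays 59.8% ± 1.17 of non-control spots were well above background (SD, n = 4), against 70.7% ± 1.16 on the Eucommia arrays. Each group lay on a slide of its own, so slide and group cannot be told apart in any value below. Arrays of a group correlated at 0.985 to 0.990 (control) and 0.990 to 0.994 (Eucommia) over genes, and arrays of different groups at 0.962 to 0.973.

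Of 24194 genes tested, 4505 were higher and 1481 lower in the Eucommia group. The filter lets in genes seen on 1 slide alone: 2009 genes were not above background on any control array, 1494 of them called higher, against 3 on no Eucommia array. The limit itself differed: the lowest signal well above background was 12.7 ± 1.05 raw units on control and 5.90 ± 0.15 on Eucommia arrays (SD, n = 4). Without the filter 5240 were higher and 7032 lower (42.7% higher). Those counts include probes at the floor, and the lowest signal was 2.51 ± 0.21 raw units on control and 1.17 ± 0.03 on Eucommia arrays (SD, n = 4). Undetected probes can thus come out lower on the Eucommia arrays through the floor alone. With the filter the higher genes were mostly dim. Among the 15443 genes with a mean signal under the arrays' 75th percentile, 4177 were higher and 966 lower, and among the 8751 brighter genes 328 were higher and 515 lower. Genes for odorant and other sensory receptors, known from the nose and tongue, stood out: 325 of 401 tested were higher and 0 lower, with a median log2 fold change of 1.61 at a median log2 signal of -4.13. They were not higher as a whole without the filter on dim probes, where 387 of 1105 were higher and 336 lower. That set includes genes at the floor, which was lower on the Eucommia arrays, so it cannot decide whether they rose. Among those above background on all arrays 81 of 99 were higher and 0 lower (median 1.30). With normexp background correction the median was 0.31, and without 1 of the Eucommia arrays (replicate 1, 2, 3 or 4) 123, 120, 127 and 125 of 193 were higher. Groups did not overlap at 28.6% of genes, where chance gives 2.86%. The higher share of called genes was 75.3% and changed with the scaling, to 59.2% with quantile normalization, 59.9% with normexp and quantile normalization, and 32.7% with median centring. Median centring moved the median log2 fold change of all genes from 0.02 to -0.23. Without 1 of the Eucommia arrays the count of called genes fell from 5986 to between 3214 (without replicate 2) and 3718 (without replicate 4), with 3590 without replicate 1 and 3457 without replicate 3. The filter still asked for 4 arrays in these fits. Genes seen on the Eucommia arrays alone, sensory receptor genes included, were therefore no longer tested, and the counts cover fewer genes.

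**Figure D1:**
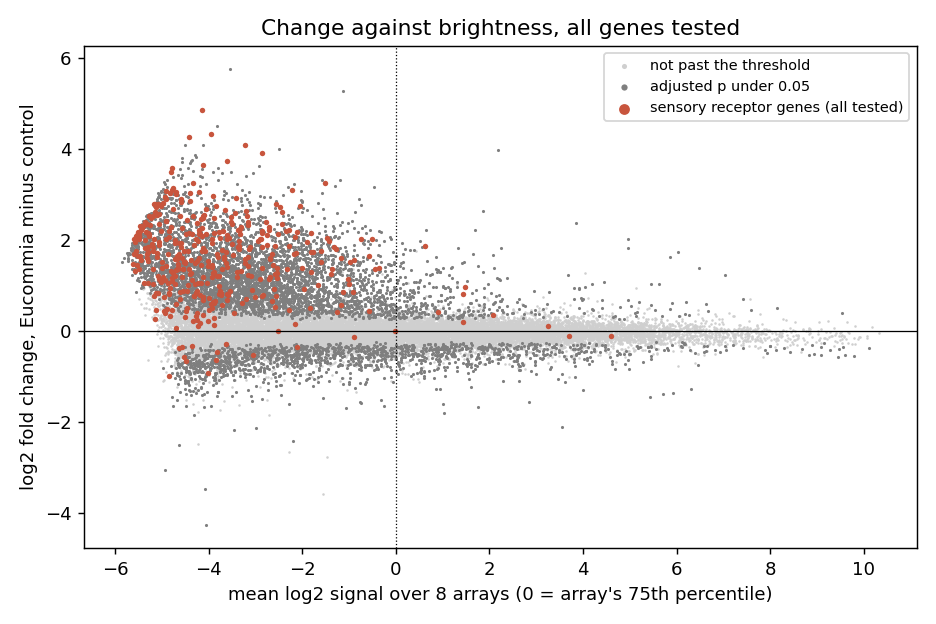
Log2 fold change (Eucommia minus control) of each of 24194 genes against its mean log2 signal over 8 arrays, where 0 is the array's 75th percentile. Points past the threshold are dark grey and the 401 sensory receptor genes are orange; the higher genes lie mostly left of 0.

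Of the 10 largest increases, 6 were in genes not well above background on any control array. Serpini2, a serine protease inhibitor, was at least 12.6-fold higher (adjusted p = 2.87e-08 by limma), and Or52n2f, an odorant receptor, at least 10.6-fold. Or52r1c was at least 6.08-fold, the vomeronasal receptor Vom2r47 at least 5.78-fold, Or52r1 at least 4.09-fold and the potassium channel Kcnh7 at least 3.86-fold higher. These bounds hold for the processed signal only. With normexp and quantile normalization, where the added offset shrinks dim folds, the log2 fold changes of Serpini2, Or52n2f, Or52r1c, Vom2r47, Or52r1 and Kcnh7 were 1.76, 1.36, 1.12, 0.94, 0.87 and 0.65. Glycam1, an adhesion molecule of lymph node vessels, rose by a log2 value of 5.27 ± 0.28 (SE), and the ubiquitin ligase Hecw1 by 3.98 ± 0.12, from 0.20 ± 0.22 to 4.18 ± 0.10 (SD, n = 4). Or12d2 (4.09 ± 0.83) and Or52s19 (3.75 ± 0.56) were well above background on 1 control array each, so the sizes of their changes rest on values near the floor. Over the settings the lowest log2 fold changes were 1.12 for Or12d2, 1.05 for Or52s19 and 3.23 for Glycam1.

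By the processed signal the largest decreases were in RT1-A3, a class I histocompatibility gene (log2 fold change -4.27 ± 1.01 SE, adjusted p = 0.0137), and then in genes with smaller changes. These were Zfp458 (-1.65), Gimd1 (-1.64), the ribosomal protein gene Rps26 (-1.59), the somatostatin receptor Sstr4 (-1.57), Rpl37al2 (-1.57), the phosphatase Ptpre (-1.53), the interferon-induced Oasl (-1.45), Ss18l1 (-1.41) and Apol7b (-1.39). RT1-A3 was well above background on 4 control arrays and 1 Eucommia array, so the size of its change rests on values near the floor. The order of these genes holds for the processed signal only. Over the alternatives the log2 fold change of RT1-A3 ran from -5.48 to -0.84, while that of Rps26 stayed at -1.31 or below and that of Rpl37al2 at -1.39 or below. With normexp that of Zfp458 was -0.34, Apol7b -0.31, Oasl -0.20 and Ss18l1 -0.19, and the last 2 did not pass (adjusted p by limma 0.0815 and 0.0570). Oasl was above background on 3 control arrays and 1 Eucommia array, so its difference is partly one of values near the floor. Gimd1 passed in 2 of the 8 fits that left 1 array out, and Apol7b in 5.

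Among genes of mitochondrial beta-oxidation, 3 of 22 measured were higher and 0 lower. Cpt1a, which forms acylcarnitines for import into mitochondria, rose by 0.47 ± 0.14 (log2, SE; adjusted p = 0.0337). Cpt2, its partner on the inner membrane, rose by 0.41 ± 0.11 (adjusted p = 0.0299), and Acadvl, the very-long-chain acyl-CoA dehydrogenase, by 0.38 ± 0.11 (adjusted p = 0.0360). Acad9 had a value of -0.31 and did not pass (adjusted p = 0.0616). Adjusted over the list alone, 0 of the 22 members passed. The list as a whole had a median of 0.02 and a mean of 0.04 and did not pass camera (adjusted p = 0.749, and 0.851 with an estimated correlation). The camera test, which compares a list with all other genes tested, pointed down. Each of the 3 calls was lost in some of the fits that left 1 array out: Cpt1a did not pass without control replicate 1 or 4 or Eucommia replicate 1, 2 or 3 (adjusted p by limma 0.0597 to 0.107). Cpt2 did not without control replicate 3 or 4 or Eucommia replicate 2, 3 or 4 (0.0505 to 0.0981), and Acadvl not without any control array or Eucommia replicate 2 or 3 (0.0635 to 0.0811). Over all 23 settings Cpt1a, Cpt2 and Acadvl passed in 17, 14 and 13. Their lowest log2 fold changes were 0.21, 0.15 and 0.13, and their highest adjusted p by limma 0.182, 0.313 and 0.408.

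Genes of peroxisomal beta- and alpha-oxidation went both ways, with 4 of 21 higher and 3 lower, the same counts when adjusted over the list alone. Hacl1, a lyase of alpha-oxidation, rose by 0.49 ± 0.14 (log2, SE; adjusted p = 0.0328 by limma), Ech1 by 0.44 ± 0.13 and Ehhadh, the bifunctional enzyme, by 0.39 ± 0.11. Hacl1 had -0.25 by its other probe and 0.12 as a mean over its 2 probes. Over the settings its adjusted p by limma reached 0.594. Ehhadh had 0.14 at the lowest over the settings, with an adjusted p by limma of up to 0.350. Scp2, a thiolase and sterol carrier, had a log2 fold change of -0.36 ± 0.10, the acyl-CoA oxidase Acox3 -0.49 ± 0.15 and Pecr -0.28 ± 0.09. Ech1, Acox3 and Pecr were named after their values were seen. The list median was -0.01, its mean was 0.06, and the test did not pass (adjusted p = 0.660, and 0.851 with an estimated correlation). Without single arrays Hacl1 lost its call in 4 of 8 fits (control replicate 3, Eucommia replicates 2, 3 and 4, adjusted p up to 0.103), Ehhadh in 6 (all but control replicate 1 and Eucommia replicate 4, up to 0.110) and Scp2 in 5 (control replicates 1 and 3, Eucommia replicates 1, 2 and 3, up to 0.0804).

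In omega-oxidation, 1 of 13 genes was lower and 0 higher: the fatty acid hydroxylase Cyp4a3 had a log2 fold change of -0.30 ± 0.09 (adjusted p = 0.0330), and adjusted over the list alone 0 passed. Without control replicate 1 or 3 or Eucommia replicate 1, 2 or 3 Cyp4a3 did not pass (adjusted p 0.0585 to 0.0966). Cyp4a1 (0.34) and Cyp4f1 (-0.20) did not pass, nor did Cyp4v3 (-3.57 ± 2.15 SE), whose arrays differed within each group. The list median was -0.05, its mean -0.36 and its adjusted p 0.219, or 0.665 with an estimated correlation.

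**Figure D2:**
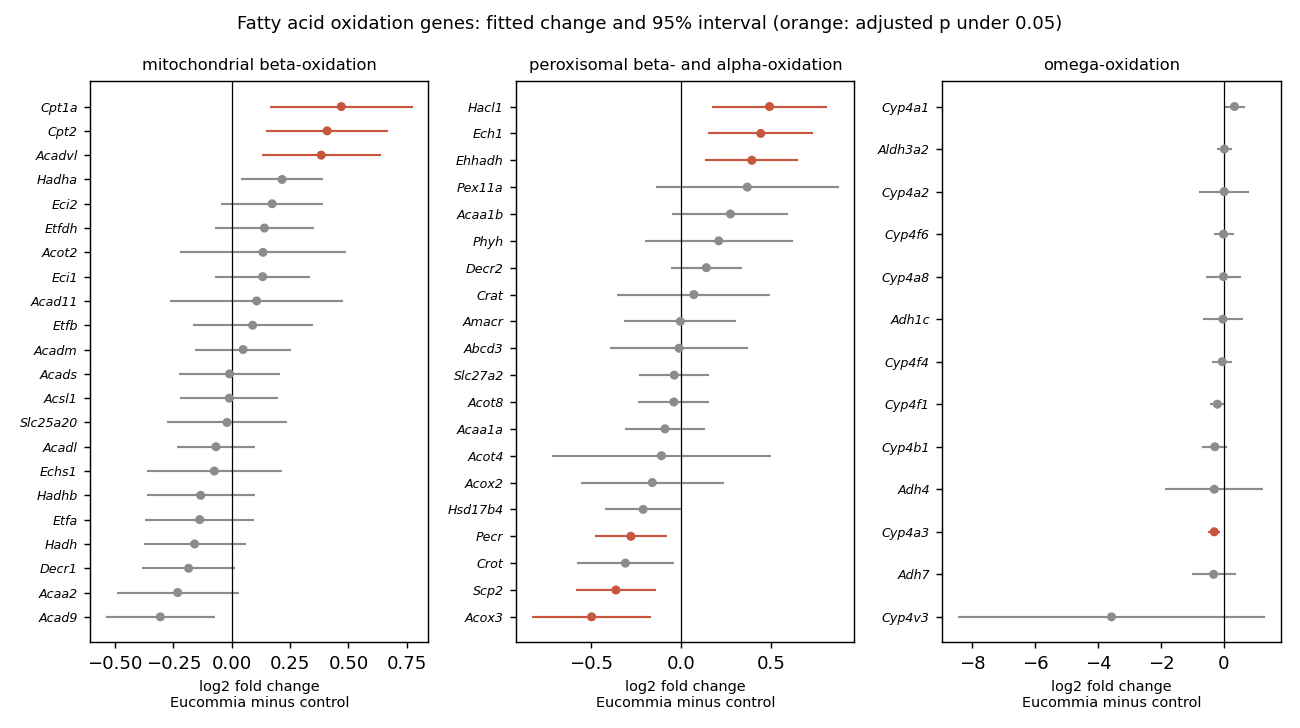
Log2 fold change (x axis, Eucommia minus control) of measured genes of the 3 fatty acid oxidation lists (22 mitochondrial, 20 of the 21 peroxisomal with 1 not reported here, 13 omega), with 95% intervals of the fit. Orange genes are past the threshold; Cpt1a, Cpt2 and Acadvl lie right of 0, and the called peroxisomal genes lie on both sides.

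Genes of lipid and sugar handling outside oxidation were mixed. In fatty acid synthesis 1 of 20 was higher and 2 lower: Mid1ip1, an activator of acetyl-CoA carboxylase, had -0.95 ± 0.12 and Fasn, the fatty acid synthase, -0.69 ± 0.19, while Acaca, the carboxylase itself, rose by 1.12 ± 0.15. Fasn was named after its values were seen. Among other PPAR-alpha targets 3 of 28 were lower and 0 higher, with Fabp1, the liver fatty acid carrier, at -0.52 ± 0.10 and Slc25a42 at -0.52 ± 0.14. In glycogen metabolism 3 of 15 were lower, with the phosphorylase Pygl at -1.11 ± 0.17 and Gyg1, the glycogen primer, at -0.56 ± 0.12. Adjusted over each list alone, the counts were 1 higher and 2 lower, 1 lower, and 2 lower. None of these 3 lists passed camera (adjusted p = 0.150, 0.219 and 0.0517), though glycogen metabolism passed fry (adjusted p = 0.0194). Pdha1, of the pyruvate dehydrogenase complex, had -0.74 ± 0.11, the ketone body enzyme Bdh1 -0.36 ± 0.09, and Apoe, an apolipoprotein, -0.38 ± 0.10. Of the 8 fits that left 1 array out, Slc25a42 and Bdh1 passed in 5 and Apoe in 4. Mogat2, which acylates monoacylglycerol, rose by 1.78 ± 0.15. Acaca and Mogat2 were dim, at mean log2 signals of -1.48 and -0.89, while Mid1ip1 lay at 3.54. Of all genes from -2 to 0, 16.1% were higher and 6.41% lower, so rises were more common than decreases in that range. Over the settings the lowest log2 fold changes of Acaca and Mogat2 were 0.67 and 1.28. In bile acid metabolism the receptor Nr1h4 rose by 0.39 ± 0.09 and the transporter Slc51a was at least 3.65-fold higher by the processed signal (0.58 on the log2 scale with normexp and quantile normalization). In hormone-dependent genes Igf1, the growth factor, had -0.52 ± 0.11 by its brightest probe but -0.06 as a mean over its 3 probes (adjusted p = 0.771), and Cish, a feedback inhibitor of cytokine signalling, rose by 1.25 ± 0.17.

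By camera at the preset correlation 9 of 50 lists passed, all toward lower values, and by fry none of these 9 did (adjusted p from 0.0818 for interferon-stimulated genes and antigen presentation to 0.612). With an estimated correlation 0 of the 50 passed (adjusted p = 0.665 to 0.843 for these 9). Camera compares a list with all other genes tested. Of these, genes at a mean log2 signal up to -4 had a median log2 fold change of 0.55, and those from -4 to -2 had 0.11. From 0 to 2, from 2 to 4 and above 4 the medians were -0.03, -0.03 and -0.05. A list of bright genes can thus come out lower through the dim genes it is compared with. Interferon-stimulated genes had a median log2 fold change of -0.43, with all 27 measured members negative and 6 past the threshold (adjusted p of the list 3.13e-05). Among them Psmb8, an immunoproteasome subunit, had -0.62 ± 0.09 (SE), Oasl -1.45 ± 0.35, Ifit3 -0.87 ± 0.25 and Ifit2 -0.43 ± 0.13, and 2 passed when adjusted over the list alone. Antigen presentation had a median of -0.25 over 18 genes with 3 lower: Psmb8, Cd74, the invariant chain (-0.53 ± 0.16), and the peptide transporter Tap1 (-0.49 ± 0.15), while Ciita (-0.64) did not pass. Psmb8 and Tap1 are also members of the interferon-stimulated list, so these lists are not independent. Kupffer cell and macrophage markers had a median of -0.38 over 26 genes with 2 lower, Fcgr2b (-0.45 ± 0.11) and Gpnmb (-0.72 ± 0.21), beside Marco (-1.10) and Aif1 (-0.52), which did not pass. Adjusted over each list alone, 1 and 0 members of these passed. Endoplasmic reticulum stress genes had a median of -0.28 over 27 with 3 lower, the same 3 when adjusted over the list alone: Ddit3 (-0.56 ± 0.13), Sesn2 (-0.49 ± 0.13) and Atf3 (-1.02 ± 0.28), which encode stress-induced regulators. With an estimated correlation the adjusted p of each of these 4 lists was 0.665. The macrophage list did not pass without control replicate 1 (adjusted p = 0.0522) or Eucommia replicate 1 (0.0682), and antigen presentation not without Eucommia replicate 1 (0.0682). Fits without a Eucommia array compared lists with fewer genes, as the filter still asked for 4 arrays. Among members, Tap1 and Cd74 passed in 1 of the 8 fits that left 1 array out, Ifit2 and Sesn2 in 2, and Ifit3, Gpnmb and Atf3 in 3. Oasl passed in 3 of the 4 fits that kept it.

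The other 5 lists past the threshold had small medians, and none of them passed camera among bright genes (adjusted p = 0.0592 to 0.502) or after cyclic loess (0.104 to 0.654). Cholesterol synthesis (-0.15, 2 of 26 lower) included Ggps1, a prenyl diphosphate synthase, at -0.49 ± 0.10. Acute-phase proteins (-0.15) had 2 lower and 2 higher of 31, with A2m at -0.59 ± 0.14, Serpina3n at -0.27 ± 0.08, and the signalling inhibitor Socs3 and Steap4 higher by 1.85 ± 0.20 and 0.74 ± 0.23. Socs3 passed in all 22 settings with a value, with 0.81 as its lowest log2 fold change. Amino acid breakdown and the urea cycle (-0.10, 2 of 43 lower) included Hgd at -0.46 ± 0.08 and Otc, of the urea cycle, at -0.43 ± 0.10. Cytosolic ribosomal proteins (-0.06) had 3 of 73 lower, with Rpl38 at -0.33 ± 0.10 and Rps27a at -0.43 ± 0.13 beside Rps26. The respiratory chain (-0.05) had 3 lower and 1 higher of 57, with Cox7c at -0.53 ± 0.11, Ndufa1 at -0.30 ± 0.09 and Atp5pf at 0.32 ± 0.09. With an estimated correlation their adjusted p was 0.665 (cholesterol, acute-phase, amino acids), 0.843 (ribosomal) and 0.825 (respiratory chain). Adjusted over each list alone, 2 passed in cholesterol synthesis, 1 lower and 1 higher among acute-phase proteins, 2 in amino acid breakdown, 1 ribosomal and 2 lower in the respiratory chain. Calls were lost without control replicate 1 (cholesterol 0.158, amino acids 0.138), control replicate 2 (ribosomal 0.0869, respiratory chain 0.0806), and control replicate 3 or 4 (acute-phase 0.0853, 0.0627). Eucommia replicate 1 ended the call of all 5 (0.212 to 0.326), and so did replicate 2 (0.104 to 0.369). Replicate 3 ended that of ribosomal proteins (0.112), the respiratory chain (0.174) and acute-phase proteins (0.0680), and replicate 4 that of cholesterol synthesis (0.0748) and acute-phase proteins (0.0756). In fits without a Eucommia array, lists were again compared with fewer genes. The median moved away from 0 for cholesterol synthesis without Eucommia replicate 2 (-0.157) or 4 (-0.187). It also did for acute-phase proteins without replicate 4 (-0.186) and the respiratory chain without replicate 1 (-0.0489). In the other fits without a Eucommia array that ended a call, the median moved toward 0. Serpina3n passed in 0 of the 8 fits Rps27a and Atp5pf in 1, and Rpl38, Ndufa1 and Steap4 in 3.

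**Figure D3:**
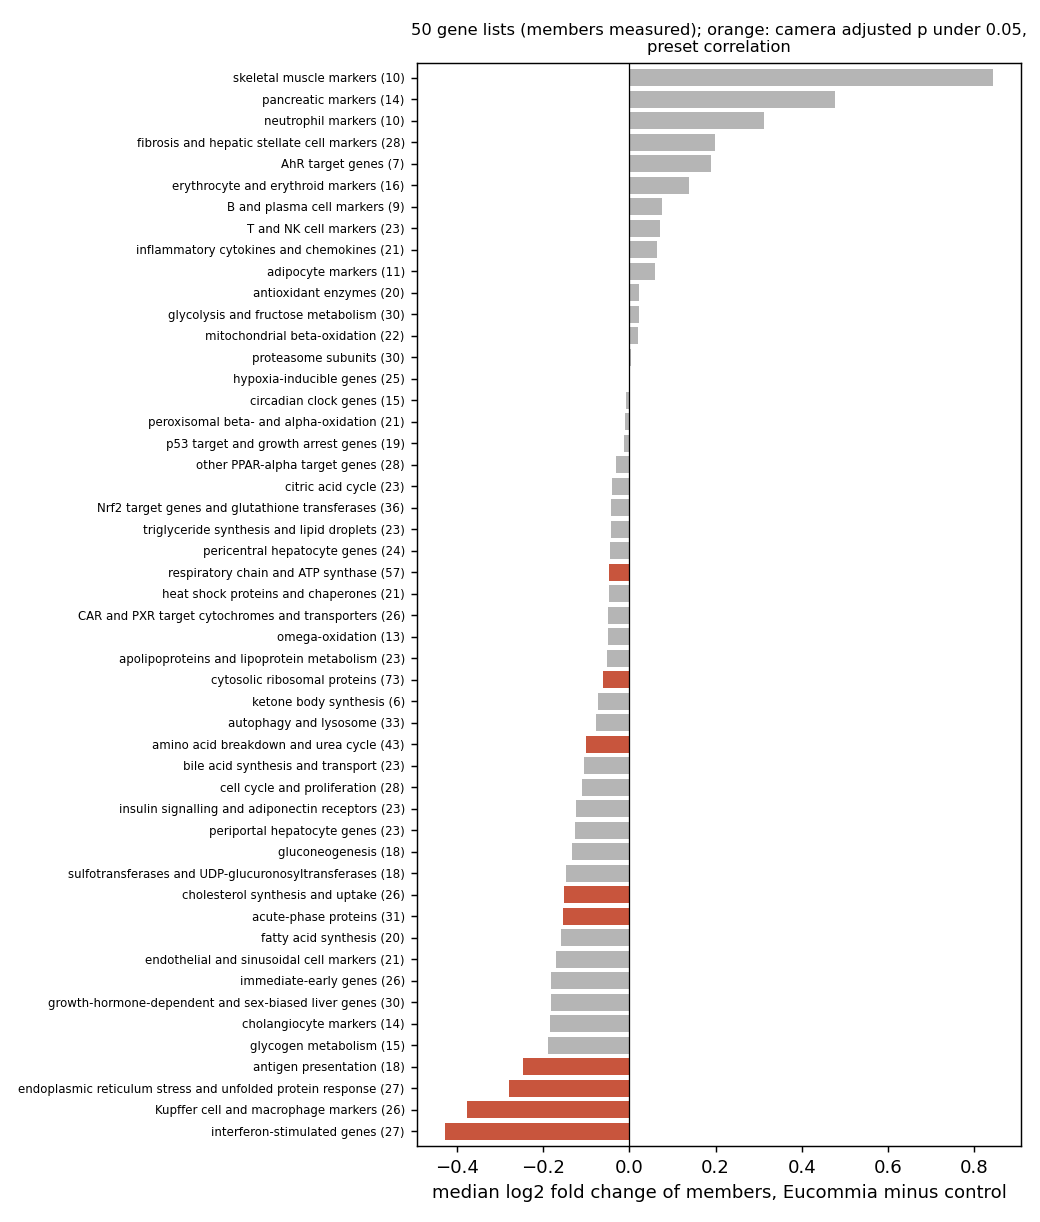
Median log2 fold change (Eucommia minus control) of the measured members of 50 gene lists, with the number of members in brackets. Orange lists passed camera at the preset correlation; all 9 lie left of 0, from -0.43 to -0.05.

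**Figure D4:**
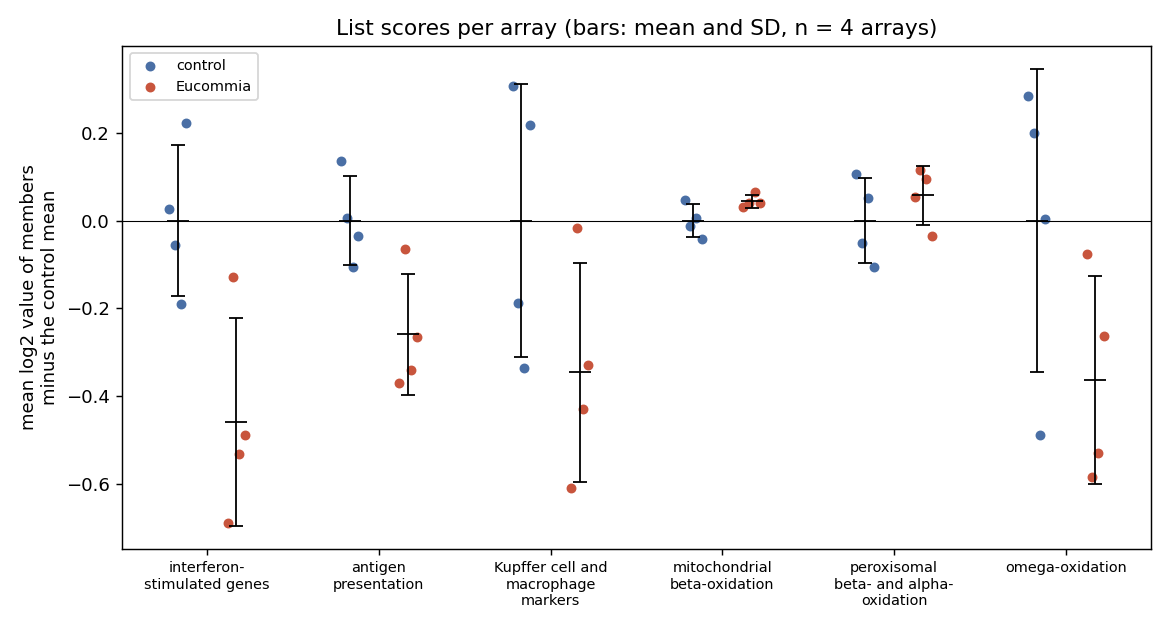
Mean log2 value of a list's members on each array, minus the control mean, for 6 lists. Points are arrays, and bars give the mean and SD (n = 4 arrays per group); for interferon-stimulated genes the Eucommia arrays ran from -0.69 to -0.13 and the control arrays from -0.19 to 0.22.

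Pancreatic markers had 6 of 14 higher and 0 lower, with the digestive enzymes Ctrb1 at 1.79 ± 0.15 and Cela2a at 1.11 ± 0.10, skeletal muscle markers 5 of 10 higher and 1 lower, with Mb, the muscle oxygen carrier, at 0.97 ± 0.09, and neutrophil markers 5 of 10 higher and 0 lower, with the granule protease Prtn3 at 1.97 ± 0.11. These lists are mostly dim, with 1 of 14, 1 of 10 and 2 of 10 members at or above the 75th percentile. Of all genes, 40.4% were higher at a mean log2 signal up to -4, 28.8% from -4 to -2, 16.1% from -2 to 0 and 5.49% from 0 to 2. Prtn3 lay at -0.26, Ctrb1 at 0.31, Mb at 0.47 and Cela2a at -3.49. Cela2a had 0.24 with normexp and quantile normalization. None passed camera in the main setting (adjusted p = 0.0505, 0.150 and 0.0764). In 22 other settings at the preset correlation, pancreatic markers passed in 12, muscle markers in 0 and neutrophil markers in 3. With an estimated correlation the adjusted p was 0.665 for each. By fry, which does not compare a list with other genes, their adjusted p was 0.00916, 0.0122 and 0.00187. Adjusted over each list alone, 6 pancreatic, 6 muscle and 5 neutrophil markers were higher and 2 muscle markers lower. T and NK cell markers had 4 of 23 higher, including Lck at 1.13 ± 0.12 and Cd8b at 1.41 ± 0.15, and among bright genes alone 5 of its members passed camera as a list (median 0.29, adjusted p = 0.0325). Endothelial markers had 5 higher and 3 lower of 21, with Cdh5 at 1.01 ± 0.09 (0.40 with normexp and quantile normalization, where Lck had 0.40 and Cd8b 0.56), a median of -0.17 and a mean of 0.04. Fibrosis and stellate cell markers had 2 of 28 higher, the collagen gene Col1a1 at 0.83 ± 0.16 and Timp1 at 0.42 ± 0.12. Col1a1 did not pass as a mean over its 2 probes (0.31, adjusted p = 0.0827), and Timp1 passed in 3 of the 8 fits that left 1 array out. Adjusted p of these lists was 0.450, 0.495 and 0.710, and adjusted over each list alone 4, 6 and 1 were higher and 0, 5 and 0 lower.

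Spike-in RNAs, added in the same amounts to every array, also differed between the slides after scaling. Each array's 75th percentile of non-control signal was subtracted from them. It was 229 ± 8.26 raw units on Eucommia and 250 ± 23.4 on control arrays (SD, n = 4). A small shift shared by all spike-in RNAs can therefore come from the scaling. The 3 dim ones were on average 0.67 higher (log2) on the Eucommia arrays, with a standard error of 0.12 between them, and the 6 bright ones 0.14 higher. The bright ones ran from -0.17 to 0.37, and the remaining spike-in RNA, at a mean log2 signal of -0.48, was 0.29 higher. Some called oxidation genes changed by less than the largest of these (Scp2 -0.36, Cyp4a3 -0.30, Pecr -0.28) and others by more (Hacl1 0.49, Cpt1a 0.47). Of the dim ones 2 were above background on only 1.56% and 3.12% of control spots, so their differences are between values near the floor; the third, at 53.1%, differed by 0.44.

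**Figure D5:**
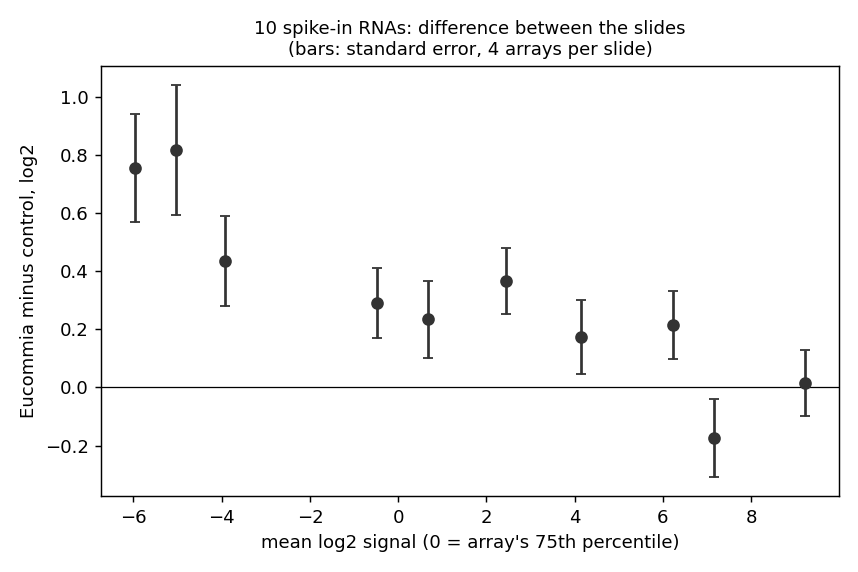
Difference in log2 signal of 10 spike-in RNAs between the slides (Eucommia minus control, with standard errors over 4 arrays per slide) against their mean log2 signal. The dimmest 3 differ by 0.44 to 0.82.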

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

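In 312 groups of 4 arrays (named genes and 5 list scores) the most distant array was set against the range of its group. It stood apart in 16, where chance gives about 15.6. These are reported as log2 values without an explanation.

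On the control side Or12d2 was -2.35 on replicate 3 (others -6.51 to -5.90), Cyp4v3 -5.68 on replicate 3 (others 1.81 to 2.86), Gimd1 1.75 on replicate 4 (others 0.12 to 0.27) and Ptpre -1.39 on replicate 4 (others -2.74 to -2.52). Idh3a was 0.24 on replicate 1 (others 0.04 to 0.05). Replicate 2 stood apart for G6pc3 (-2.01, others -1.80 to -1.76), Atp5pf (6.03, others 5.83 to 5.86) and Mcrip1 (0.77, others 0.50 to 0.54).

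On the Eucommia side Cyp4v3 was 1.63 on replicate 1 (others -5.05 to -4.98) and RT1-A3 was -2.57 on replicate 1 (others -7.57 to -7.21). Replicate 3 stood apart for Lgr5 (-3.23, others -2.28 to -2.23) and Or6z1 (1.18, others 1.68 to 1.69). Replicate 4 stood apart for Ss18l1 (-5.23, others -4.76 to -4.68), Nqo1 (-2.83, others -1.68 to -1.64), Hsp90aa1 (6.0, others 6.74 to 6.79) and Pdap1 (-0.31, others 0.46 to 0.56).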

How the results depend on the processing

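The bright-gene restriction and cyclic loess were chosen after seeing the data. No slide held both groups (0 of 2), so no slide block could be fitted, and slide and group cannot be told apart for the count of genes. Signal over background limits dim genes most. Of 5986 genes past the threshold, the count was 11342 with median centring (5186 shared), 12272 without the filter on dim probes, 3575 with probes above background on all arrays and 713 among bright genes (fewer genes tested). Higher genes numbered 2261 with probes above background on all arrays and 304 among bright genes. Lower genes numbered 2796 with quantile normalization, 7635 with median centring, 2582 with normexp and quantile normalization, 7032 without the filter, 409 among bright genes and 2297 with cyclic loess. Without 1 array, genes past the threshold ran from 3214 to 5600, higher genes from 2456 to 4499 and lower genes from 758 to 1282. The cause was not tested.

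Gene lists past the threshold numbered 1 with quantile normalization, 1 with normexp and quantile normalization, 0 without the filter, 5 with probes above background on all arrays, 18 with every probe on its own, 5 among bright genes (4 of the 9, and T and NK cell markers toward higher values), 3 with cyclic loess and 0 with an estimated correlation, and 3 to 11 without 1 array. The interferon-stimulated list passed in 22 of 23 settings at the preset correlation, with medians from -0.68 to -0.31 and adjusted p from 1.57e-06 to 0.153.

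No oxidation list passed in any setting. The median of mitochondrial beta-oxidation turned negative with median centring (-0.236), the mean over probes (-0.0150) and every probe on its own (-0.0102), and ran from 0.0107 to 0.0434 without 1 array. That of peroxisomal oxidation turned positive with quantile normalization (0.0984), the percentile over probes above background on all arrays (0.0139), normexp (0.0547), normexp and quantile normalization (0.170), the mean over probes (0.0319), every probe on its own (0.0395), array weights (0.0714) and cyclic loess (0.0639), and ran from -0.0290 to 0.0955 without 1 array. That of omega-oxidation turned positive with quantile normalization (0.0278) and cyclic loess (0.0254), and ran from -0.210 to -0.0465 without 1 array. The cause was not tested.

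Of the named genes 3 turned: Psmc2 (-0.00586 with median centring), Cyp2c7 (0.0761 with normexp and quantile normalization) and Flt1 (-0.34 with probes above background on all arrays, where another probe stands for the gene). Over all settings, named-gene values kept direction and call 2941 times, lost the call 292 times and gained it 83 times.

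With the replicate number as a block, 5003 genes passed, 4053 higher and 950 lower, and 11 lists. Residuals of same-numbered arrays correlated at -0.04, -0.03, -0.06 and -0.10, and 0 of 8 arrays correlated best with its own number, so the numbers do not pair the samples.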

Other observations

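The tests on spike-in RNAs, on constant background, on macrophage markers and on slides were chosen after the result was seen, as was the requirement that an interval lie beyond a bound. The bootstrap intervals below resample probes or genes, not arrays, so they do not measure the spread between samples. Bright genes (mean signal at or above the arrays' 75th percentile) held other large changes, chosen after their values were seen. Higher were Misp3 (log2 fold change 2.63), Cav3, a caveolar protein of muscle (2.23), Mcrip1 (2.22), Rbm38 (1.85), Foxe1, a transcription factor known from the thyroid (1.82), and Crhr2, a stress hormone receptor (1.69). Lower were RT1-CE16, a class I histocompatibility gene (-1.35), Krcc1 (-1.29), the pheromone-carrier gene Mup4 (-1.27), Surf6 (-1.06), Pdap1 (-1.03) and Dusp1, an immediate-early phosphatase (-1.01). Each of these passed limma's adjusted threshold. Of the 8 fits that left 1 array out, Surf6 passed in 4, Dusp1 in 5, RT1-CE16 in 6 and the other bright genes named here in all 8. Over the settings Surf6 had -0.54 at the weakest.

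Dim genes, sensory receptors among them, were higher on the Eucommia arrays among probes that passed the filter, which 206 of the 401 sensory receptor genes passed through the Eucommia arrays alone. The sensory median was 0.07 without the filter and 1.30 over the 99 genes above background on all arrays. The first value includes genes at the floor, which was lower on the Eucommia arrays. Over all 6993 probes with a mean log2 signal from -3 to -1, detected or not, the median rise was 0.41 raw signal units with arrays scaled to one 75th percentile (95% bootstrap interval -0.05 to 0.77) and -4.74 unscaled. For probes in this range, a constant background of 4 units or more left on the Eucommia arrays is argued against. The range lies above the sensory median of -4.13, and for dimmer probes such a background stays open. The median signal of all spots was 30.0 ± 1.65 raw units on Eucommia and 27.4 ± 1.24 on control arrays (SD, n = 4). The 75th percentile was 229 ± 8.26 and 250 ± 23.4. A different response of the 2 slides to the same amount of RNA stays open, since the shift of 0.67 in dim spike-in RNAs rests on 2 near the floor and 1 above it. More RNA of these genes in the liver stays open too: 48.3% of 120 other probes were higher and past the threshold (exact interval 39.1% to 57.6%), under the 50% set beforehand as counting against it. All dim probes gave 30.7%, but that share is not matched for brightness. The other probes were by rule dimmer than the probe that stands for the gene. Of all genes at a mean log2 signal up to -4, 40.4% were higher, so the comparison with 30.7% lends no support. Calls of other kinds were repeated less often: by 16.1% of 62 other probes of bright higher genes and 18.2% of 198 of lower genes. Probes of one gene had the same sign in 61.1% (dimmest pairs), 63.3% and 66.9% (brightest pairs) of cases. Most single-gene calls therefore rest on 1 probe.

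Interferon-stimulated and antigen presentation genes had lower medians with Eucommia, past the threshold by camera at the preset correlation only (adjusted p = 0.665 with an estimated correlation and 0.0818 by fry for each list). An intensity trend between the slides is argued against for the interferon-stimulated list on these arrays. Its median was -0.42 after cyclic loess (bootstrap interval over its genes -0.52 to -0.36). The trend stays open for antigen presentation, which had -0.18 and lost its call (adjusted p = 0.0700 by camera). One high control animal is argued against by the median of -0.31 that remained at most without any 1 control array. Fewer macrophages in the piece of liver stay open: the interferon-stimulated median minus the macrophage median was -0.0521 (interval -0.23 to 0.10). Chance could not be excluded either, as 2 of 35 splits of the arrays, the real one included, gave an interferon-stimulated median as far from 0. The highest of the other splits gave 0.48, and the slides stay open as well.

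Called fatty acid oxidation genes went both ways. Differences between slides at single probes cannot be told apart from changes of the genes, because the 11 called genes had only 2 other kept probes, 50% of them with the same sign. Acadvl's other probe had a log2 fold change of 0.04 and that of Hacl1 -0.25.

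Over the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many genes past the threshold, higher or lower, and the highest other split gave 2, against 5986, 4505 and 1481. The splits cannot decide about chance for these counts, as 1 of 35 is the smallest share they can give. The real split is also the split by slide, and every other split mixes the slides within its groups. Chance cannot be excluded for the 9 lists past the threshold, since 22 splits, the real one included, gave as many, and the highest other count was 20. The same holds for the median shifts of mitochondrial (16 splits as large, highest other 0.06 against 0.02), peroxisomal (31 splits, 0.17 against -0.01) and omega-oxidation (15 splits, 0.16 against -0.05). These counts include the real split too.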
